A study of Mus musculus with 14 samples.

How the data were processed

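RNA sequencing was measured in 14 mouse brain samples on the C57Bl/6 background at 6 months of age. They were dissected striatum, with 3 wildtype (WT) and 3 Thap1 conditional knockout (cKO) samples, and cerebellum, with 4 WT and 4 cKO samples. The controls were littermates, per the labels' series description. The Cre driver, the deleted part of Thap1 and the sequencing batches are not given in the sources used here. Nothing in those sources says whether a tissue pair came from 1 animal, or that each replicate is a separate animal, so p-values measure the spread between these samples.

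The authors deposited 1 table of raw read counts per sample, with 23337 gene symbols in each, none of them a class of unassigned reads. Per the submitters' processing notes, cutadapt 1.13, STAR, HTSeq 0.6.1p1 and DESeq2 were used with genome build mm10, without a statement of their order. The STAR version, the gene annotation and the strand setting of the counting are not given in the sources used here. The counts of genes that overlap another gene, antisense genes included, are therefore uncertain. Library totals ran from 12595941 to 14258141 counts in striatum and from 19458954 to 28099205 in cerebellum.

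Counts were normalised with TMM factors in edgeR 4.0.16 (R 4.3.3), and genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15. Expression levels are CPM, the count of a gene scaled by its TMM-adjusted library size, as mean ± SD over the samples of a group. Genotypes were compared within each tissue with edgeR's robust quasi-likelihood test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Positive log2 fold changes mean higher in cKO, and each standard error (SE) was the log2 fold change divided by the square root of its F statistic. The genotype by tissue interaction was the cerebellar minus the striatal log2 fold change, tested in 1 model of all 14 samples. Thap1 itself was also compared with an exact two-sided permutation test of CPM, and the mean log2 CPM over the myelin list in the same way. Calls shared by the tissues were compared with independent lists by Fisher's exact test.

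The 35 gene lists, 16 of cell type or region markers and 19 of pathways, were written before the data were examined, as were the main tests, the rule for naming genes and all but 1 of the other settings tried. The tests of linkage to chromosome 8 and of scaling with the loss of Thap1 were chosen after their results were seen. Lists with at least 2 measured members were tested with camera on log2 CPM (prior count 2) at an inter-gene correlation of 0.01. Camera with the correlation estimated for each list and fry were run beside it (limma 3.58.1). The naming rule took, in each tissue, Thap1 and then up to 12 risen and 12 fallen genes with the smallest p. These had to be called, have a mean CPM of at least 1 and no overlap between genotypes, and predicted or unnamed symbols were skipped. It also took 6 genes per direction for the interaction, 10 genes called in both tissues, and up to 4 members per list, called ones first. Mbp was added after its value was seen. Some genes that the rule takes are not reported here.

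Coordinates are from GENCODE vM21 on GRCm38, the assembly called mm10. Of the symbols, 89.6% matched by current symbol, 8.19% through a synonym and 2.19% not at all. Exon length is the union of a gene's annotated exons.

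The models were tested on simulated counts with the real means, dispersions and library sizes, in 5 runs of 200 changed genes each. At a 2-fold change, 72.4% of changed genes were recovered in striatum (13963 to 13978 genes tested), 93.3% in cerebellum (14675 to 14697) and 62.5% for the interaction (15290 to 15316). At a 1.25-fold change the shares were 2.41%, 56.3% and 2.69%. False calls made up 9.70% of calls in striatum and 8.84% in cerebellum, above the share of 0.05 that the threshold sets, and 3.60% in the interaction. No call had the wrong sign. The interaction runs drew both tissues with the same dispersion of each gene. Fitted apart, the common biological coefficient of variation between samples was 0.135 in striatum and 0.0722 in cerebellum. In all runs genes were drawn independently of each other. The 3.60% therefore does not show how often real interaction calls are false.

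The other settings chosen before the data were examined were DESeq2's size factors, upper-quartile factors, library totals for Thap1, no low-count filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom with quality weights, a replicate block, a sex score as covariate, all samples in 1 model, an adjusted p of 0.1, and leaving out each sample in turn. Removing each library's trend with exon length was added after the data had been seen. No deposited sample was left out of the main tests.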

Results

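The transcriptomes of striatum and cerebellum were compared between WT mice and Thap1 cKO littermates at 6 months of age. THAP1 is a zinc-finger transcription factor whose mutations cause the dystonia DYT6, and both regions belong to the motor circuits studied in dystonia. The striatal libraries, 3 per genotype, held 12595941 to 13499875 counts in WT and 12659013 to 14258141 in cKO. The cerebellar libraries, 4 per genotype, held 19458954 to 24331760 counts in WT and 19860775 to 28099205 in cKO. Between 16477 and 17716 genes had at least 1 count in a library. Region markers, scaled over all 14 libraries, separated the dissections. The dopamine receptor gene Drd2 stood at 243 ± 11.6 CPM in WT striatum (SD, n = 3) and 0.757 ± 0.645 CPM in WT cerebellum (SD, n = 4). The granule cell gene Zic1 stood at 20.8 ± 3.10 CPM in WT striatum and 762 ± 60.7 CPM in WT cerebellum. Xist and Y-linked counts placed 1 male and 2 females in each striatal group, and 2 males and 2 females in each cerebellar group. Within a group, pairs of libraries differed by more than counting noise, with a chi-square per degree of freedom of at least 5.93. One striatal library, WT replicate 1, differed from the other WT striatal libraries by 27.2 and 26.9, against 6.52 between those 2. It lay apart on the first principal component of the striatal samples, which held 49.1% of their variance. It also read as the 1 male of its group, as cKO replicate 1 did in the cKO group. Striatal fits without either of these libraries therefore leave the sexes unbalanced.

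The first comparison asked whether the targeted gene was lower in the libraries labelled cKO. Thap1 (chromosome 8, 26158141 to 26164151, mm10) was lower in cKO in both tissues. In striatum it stood at 14.3 ± 1.07 CPM in WT and 5.56 ± 1.96 CPM in cKO (SD, n = 3 each), which is 38.8% of WT. In cerebellum it stood at 9.31 ± 1.245 CPM in WT and 7.36 ± 0.391 CPM in cKO (SD, n = 4 each), which is 79.0% of WT. The counts behind these levels ran from 48 to 195 in striatum and from 148 to 231 in cerebellum. The genotypes did not overlap in either tissue, and the exact two-sided permutation p was 0.1 in striatum and 0.0286 in cerebellum, in each case the smallest the design allows. In edgeR's quasi-likelihood test the log2 fold change was −1.36 (SE 0.231, adjusted p = 0.0562) in striatum and −0.34 (SE 0.10, adjusted p = 0.0488) in cerebellum. Striatal Thap1 passed without WT replicate 1 (adjusted p = 0.0248, against 0.0543 to 0.404 without another library). Cerebellar Thap1 passed without WT replicate 2 or 4 and did not pass without WT replicate 1 or 3 or any of the cKO libraries (adjusted p from 0.0659 to 0.170), or with DESeq2's size factors (0.0503) or library totals (0.0597). The difference between the tissues was 1.01 (SE 0.237, adjusted p = 0.0884) and did not pass. Which exons were deleted is not given, so reads from the undeleted part of the transcript are counted here.

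**Figure D1:**
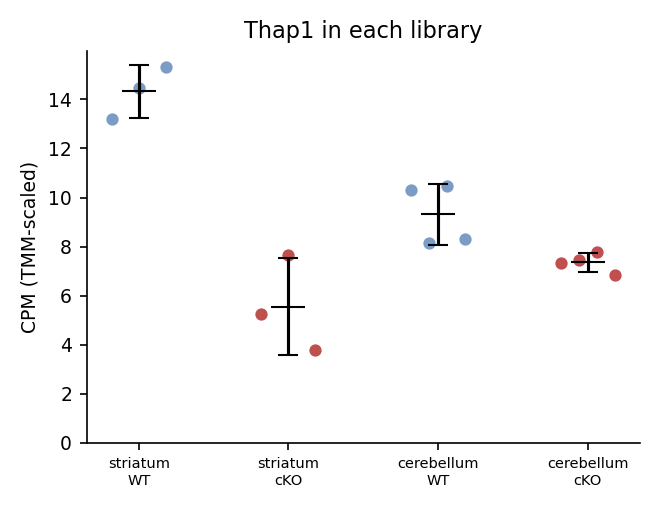
Thap1 in TMM-scaled CPM in each of the 14 libraries, by tissue and genotype; points are libraries, horizontal bars the mean and error bars the SD. Thap1 averaged 5.56 CPM in cKO against 14.3 CPM in WT striatum, and 7.36 against 9.31 CPM in cerebellum.

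In striatum, the genotype comparison asked which transcripts depend on Thap1 in the basal ganglia, and most of the genes that changed were lower in cKO. The deepest decreases were in Ech1, a peroxisomal and mitochondrial dienoyl-CoA isomerase of fatty acid oxidation, and Cradd, an adaptor of caspase-2 signalling. Ech1 fell from 38.9 ± 8.86 to 4.67 ± 0.536 CPM (SD, n = 3 each), a log2 fold change of −3.05 (SE 0.200, adjusted p = 0.000679). Cradd fell from 7.20 ± 1.59 to 1.04 ± 0.147 CPM, a log2 fold change of −2.79. Cln3, the lysosomal membrane protein mutated in juvenile Batten disease, fell to 26.8% of WT, from 13.1 ± 1.35 to 3.52 ± 0.363 CPM. Cuedc2, Zfp658, Tomm40l, Atpbd4 and Ehd3 fell to between 26.9% and 46.5% of WT. Atpbd4 is an earlier symbol of the diphthamide enzyme Dph6. Among the increases, the minor spliceosome component Snrnp35 rose from 6.42 ± 0.668 to 25.04 ± 0.134 CPM (log2 fold change 1.96, SE 0.129, adjusted p = 0.000679). Ppp2r3c, a regulatory subunit of protein phosphatase 2A, rose from 9.69 ± 0.863 to 29.5 ± 2.06 CPM. The mitochondrial alanyl-tRNA synthetase Aars2 rose from 22.2 ± 2.28 to 48.4 ± 2.01 CPM. Fam117a, Dnlz, Cyb5d2, Racgap1, Imp4 and Lrsam1 rose by log2 fold changes of 0.62 to 1.42. In all, 54 of 14080 tested genes were called by edgeR, 9 higher and 45 lower, and 24 of them changed at least 2-fold. At an unadjusted p under 0.05 there were 1020 genes. The number of calls was 3 without cKO replicate 1 and 3 without cKO replicate 3, in both cases 2 higher and 1 lower, so most were not lower there. It was 12 without WT replicate 3 and 12 without cKO replicate 2 (3 higher and 9 lower in both), and 122 without WT replicate 1 (27 higher and 95 lower). Ech1, Ppp2r3c and Snrnp35 were the genes called whichever library was left out.

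Myelin genes were among the genes that fell in striatum. All 15 measured genes of mature oligodendrocytes and myelin were lower in cKO, with a median log2 fold change of −0.82. Over all genes 6 of them fell in edgeR's test, and 15 fell when adjusted over the list alone. Mal, a proteolipid of compact myelin, fell from 444 ± 52.7 to 210 ± 21.2 CPM (SD, n = 3 each; log2 fold change −1.08, SE 0.116, adjusted p = 0.00823). The tight junction protein Cldn11 fell by 0.90, the cytoskeletal protein Ermn by 0.98 and the receptor Gpr37 by 0.83 on the log2 scale. Mbp, the most abundant member, chosen after its value was seen, had a log2 fold change of −0.59 and did not pass over all genes. Anln, which is expressed in oligodendrocytes as well as in dividing cells, fell to 48.9% of WT. Camera placed the list below other genes (adjusted p = 9.92e-22), with adjusted p = 0.634 with an estimated correlation. An exact two-sided permutation test of the libraries' mean log2 CPM over the list gave p = 0.1, the smallest the design allows. The number of called members was 0 without cKO replicate 1, 0 without cKO replicate 3, 1 without WT replicate 3, 2 without cKO replicate 2 and 9 without WT replicate 1. The median ranged from −0.87 without cKO replicate 2 to −0.71 without WT replicate 1. None of 9 oligodendrocyte precursor genes was called by edgeR, and 1 was lower when adjusted over the list alone.

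The other striatal lists held few called members. Of 5 candidate THAP1 targets, 1110034G24Rik (now Shld1, a DNA repair factor) had a log2 fold change of −2.42 and Gusb, the lysosomal beta-glucuronidase, of −1.24, and both fell, also when adjusted over the list alone (camera adjusted p = 0.0228; 0.634 with an estimated correlation). Genes of oxidative phosphorylation had a median log2 fold change of 0.36, cytosolic ribosomal protein genes 0.23 and proteasome genes 0.19. None of the 73, 67 and 31 measured members was called by edgeR, over all genes or adjusted over each list alone, although camera passed each list (adjusted p of 8.19e-12, 4.17e-06 and 1.92e-05; 0.634 for each with an estimated correlation). Without WT replicate 1 these medians were 0.08, −0.06 and 0.04, and camera passed oxidative phosphorylation (adjusted p = 0.000273) but not the ribosomal protein list (0.0511), which turned direction, or the proteasome list (0.0803). Without WT replicate 3 the medians were 0.53, 0.43 and 0.27. Choroid plexus genes had a median of 0.90 and ependymal genes of 0.41, with 0 called members among 7 and 6 by edgeR, over all genes or adjusted over each list alone (camera adjusted p of 0.0140 and 0.0415). Cell cycle, interferon response and glutamate receptor genes had medians of −0.22, −0.31 and −0.10, and astrocyte genes of 0.07 (camera adjusted p of 0.00146, 0.00743, 0.0228 and 0.0304). None of their members was called over all genes by edgeR, while 3 cell cycle genes fell and 2 astrocyte genes rose when adjusted over the list alone. These 6 lists had adjusted p = 0.634 with an estimated correlation. Without WT replicate 1 camera did not pass the ependymal (median 0.07, adjusted p = 0.855), glutamate receptor (−0.02, 0.557) or interferon response list (−0.26, 0.0511). Nor did it pass ependyma without cKO replicate 1 or 2, choroid plexus without cKO replicate 1 (median 0.42, adjusted p = 0.128), glutamate receptors without cKO replicate 1, interferon response without WT replicate 2, cell cycle without WT replicate 3, or astrocytes without WT replicate 2 or cKO replicate 2 (0.217 and 0.191). With 1 library left out, the medians ran from −0.34 to −0.16 for cell cycle, −0.45 to −0.18 for interferon response, −0.17 to −0.02 for glutamate receptor, 0.03 to 0.16 for astrocyte, 0.42 to 1.31 for choroid plexus and 0.07 to 0.71 for ependymal genes. Without WT replicate 1, 3 cell cycle genes fell over all genes (camera adjusted p = 8.45e-07) and 1 astrocyte gene rose. The candidate target list held 0 called genes without cKO replicate 1 or cKO replicate 3. It did not pass without WT replicate 2 or WT replicate 3, and its median was 0.08 without the latter and −0.09 with all libraries. The median was −0.27 without WT replicate 1 (camera adjusted p = 0.00635) and −0.39 with the length trend removed (0.00218). The ependymal list also did not pass without the low-count filter (0.0547) or, like the glutamate receptor list, with the length trend removed (0.0747 and 0.632). The astrocyte filament gene Gfap had a log2 fold change of 1.58 and an adjusted p of 0.0593. Of 18 striatal projection neuron markers and 9 interneuron markers, 0 were called by edgeR, with medians of −0.05 and 0.02. In total 11 of 32 lists passed with camera, 0 with an estimated correlation and 0 with fry. Other splits of the striatal libraries passed a median of 8 lists with camera, so a pass alone is weak evidence of a genotype effect.

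**Figure D2:**
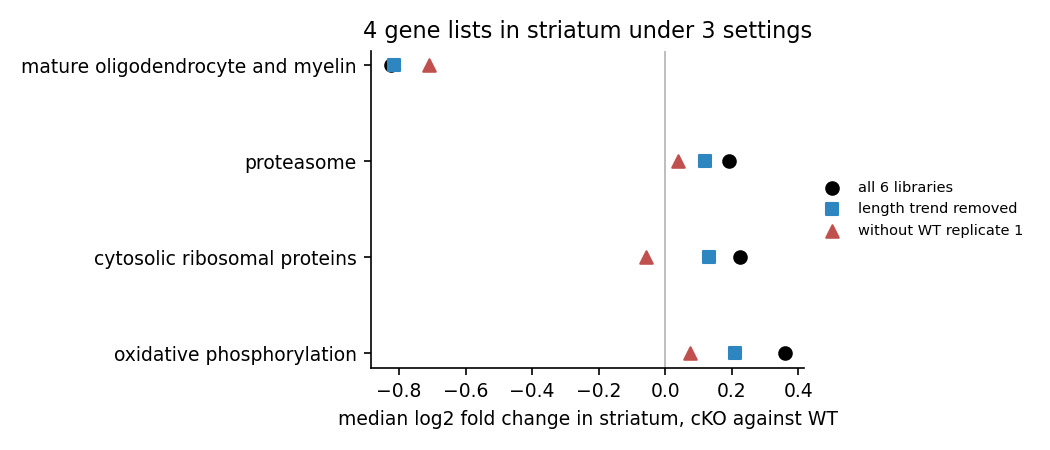
Median log2 fold change, cKO against WT, of 4 gene lists in striatum with all 6 libraries, after each library's trend with exon length was removed, and without WT replicate 1. The myelin median stays between −0.82 and −0.71, while the oxidative phosphorylation median goes from 0.36 to 0.08 without WT replicate 1.

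**Figure D3:**
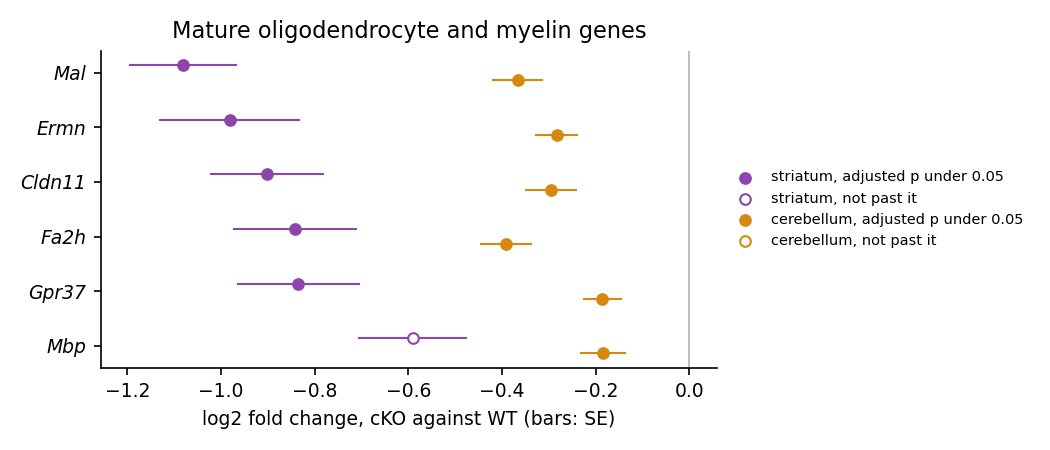
Log2 fold changes, cKO against WT, of the 6 genes of mature oligodendrocytes and myelin named in the text, in striatum and cerebellum; bars are SE and filled points passed an adjusted p of 0.05 over all genes. Every point lies below 0, with Mal at −1.08 in striatum and −0.37 in cerebellum.

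In cerebellum many more genes were called, and most changes were small. Cradd, Ech1, Cln3 and Cuedc2 fell here as well, by log2 fold changes of −2.74, −2.51, −2.03 and −1.73. Myo15, an unconventional myosin best known from hair cells, fell by 2.56 on the log2 scale, and the zinc finger gene Zfp882 by 2.90. Cuedc2 fell from 106 ± 4.52 to 31.9 ± 0.662 CPM (SD, n = 4 each; SE of the log2 fold change 0.0426, adjusted p = 2.10e-13). Cln3 fell from 15.2 ± 0.301 to 3.69 ± 0.389 CPM, Ech1 from 47.2 ± 2.27 to 8.33 ± 1.56 CPM and Myo15 from 9.85 ± 1.04 to 1.68 ± 0.174 CPM. Synpr, a synaptic vesicle protein, fell to 46.6% of WT, and Prepl, Fxyd6, Echdc2, Car4 and the T-type calcium channel gene Cacna1i fell to between 59.8% and 69.4%. Racgap1, a regulator of cytokinesis, had the smallest p among the increases and rose from 17.0 ± 0.922 to 41.8 ± 0.610 CPM (log2 fold change 1.30, SE 0.0512, adjusted p = 1.75e-10). Ppp2r3c rose to 210% of WT, the collagen receptor Ddr2 to 202%, Aars2 to 184% and Dnlz to 179%. Prpsap1, Igfbp5, Nars (the cytosolic asparaginyl-tRNA synthetase), Gpr137, Os9, Casc4 and Imp4 rose by log2 fold changes of 0.44 to 0.69. edgeR called 1121 of 14775 tested genes, 388 higher and 733 lower, with a median absolute log2 fold change of 0.24, and 41 of them changed at least 2-fold. At an unadjusted p under 0.05 there were 3327 genes. The count was 739 without WT replicate 3 and 744 without cKO replicate 2, and 251 when all 14 libraries were fitted in 1 model. Leaving out any of the other cerebellar libraries gave between 780 and 1165.

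In the cerebellum 9 of 15 myelin genes fell and 3 of 11 reactive astrocyte genes rose. All 15 myelin genes were lower in cKO and 9 fell by edgeR's test (13 adjusted over the list alone), with a median log2 fold change of −0.19. Fa2h, an enzyme of myelin galactolipid synthesis, fell by 0.39, Mal by 0.37, and Mbp, chosen after its value was seen, by 0.18 on the log2 scale. Of 9 oligodendrocyte precursor genes, Pdgfra rose, by 0.26. Of 11 reactive astrocyte genes, 3 rose and 0 fell, over all genes as well as adjusted over the list alone: Gfap to 176% of WT, complement C4b to 138% and ceruloplasmin (Cp) to 128%. Among 12 astrocyte markers Gfap and the gap junction gene Gja1 were among 3 that rose, while S100b and the glutamate transporter Slc1a3 fell. Camera passed the myelin list (adjusted p = 1.66e-08) and the reactive astrocyte list (0.00205), each with adjusted p = 0.390 with an estimated correlation. It did not pass the general astrocyte list (0.663) or the precursor list (0.126). Fry passed both the myelin and the reactive astrocyte list at an adjusted p of 0.0137. It also passed the precursor list, as higher in cKO, at an adjusted p of 0.0405. An exact two-sided permutation test of the libraries' mean log2 CPM over the myelin list gave p = 0.0286, the smallest the design allows. Meningeal genes were also higher, with Col1a2 and Igf2 called among 7 (6 adjusted over the list alone) and a median of 0.37 (camera adjusted p = 0.000547; 0.390 with an estimated correlation). Igf2 overlaps an antisense gene that was called in the same direction, so its value is uncertain. With 1 library left out, 6 to 12 myelin genes (12 without WT replicate 1), 2 to 3 reactive astrocyte genes and 1 to 4 meningeal genes were called in these directions.

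Stress response, mitochondrial and neuronal lists also held called genes in cerebellum. Of 22 integrated stress response targets 3 rose: the cystine transporter Slc7a11 by 0.40, the stress regulator Nupr1 by 0.51 and asparagine synthetase (Asns) by 0.18 on the log2 scale (4 adjusted over the list alone). Of 15 unfolded protein response genes, the endoplasmic reticulum chaperone Hsp90b1 rose by 0.26. The median log2 fold changes of these lists were 0.13 and 0.15, and camera passed both at an adjusted p of 0.00128 (0.394 and 0.496 with an estimated correlation). Of 74 oxidative phosphorylation genes 8 rose (16 adjusted over the list alone), including Cox5b by 0.23 and Cox6c by 0.16, and 1 fell (camera adjusted p = 3.87e-07; 0.390 with an estimated correlation). Among 12 granule cell markers Fat2, Reln and Grin2c fell to 82.7%, 86.2% and 87.8% of WT, and 0 rose, with 6 lower when adjusted over the list alone (camera adjusted p = 0.00330; 0.496 with an estimated correlation). Of 12 Purkinje cell markers 1, the calcium release channel Itpr1, rose to 111% of WT, and 2 did when adjusted over the list alone (camera adjusted p = 0.0110; 0.496 with an estimated correlation). Nos1 and Npy, which mark interneurons in striatum, fell to 60.7% and 74.7% of WT in cerebellum. There 4 genes of the striatal interneuron list were measured. Camera did not pass that list (adjusted p = 0.0887, or 0.394 with an estimated correlation), while fry passed it as lower in cKO (adjusted p = 0.0135). Of 5 candidate THAP1 targets 3 fell, over all genes and adjusted over the list alone: 1110034G24Rik to 14.9% of WT, Gusb to 38.9% and the proteasome subunit Psmb5 to 58.2% (camera adjusted p = 0.000547; 0.212 with an estimated correlation). The replication genes Mcm2 and Mcm3 rose to 125% and 132% of WT, and Bst2 rose alone among 13 interferon response genes. Cell cycle, proteasome, microglial and interferon lists passed with camera at adjusted p of 0.00432, 0.0148, 0.0254 and 0.0325, against 0.413, 0.661, 0.496 and 0.661 with an estimated correlation. Camera did not pass the Purkinje, proteasome, microglial and interferon lists without cKO replicate 4, nor the proteasome list without WT replicate 2, WT replicate 4 or cKO replicate 3, the microglial list without WT replicate 4, and the interferon list without WT replicate 1, WT replicate 2 or cKO replicate 1. With 1 library left out, called unfolded protein response genes numbered 8 without WT replicate 1 (camera adjusted p = 4.05e-09) and 1 in each other case. Integrated stress response genes numbered 3 to 5 (5 without WT replicate 4), and granule cell genes 2 to 7 (7 without WT replicate 2). Risen oxidative phosphorylation genes numbered 5 to 9, Purkinje cell genes 0 to 2, cell cycle genes 0 to 1 and interferon response genes 0 to 2, and the candidate targets stayed at 3. In total 13 of 34 lists passed with camera, 0 with an estimated correlation and 8 with fry. Other splits of the cerebellar libraries passed a median of 7 lists with camera.

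Most of the striatal calls were shared with the cerebellum. Of the 54 striatal calls, 38 were also called with the same sign in cerebellum, including each of the 9 genes that rose in striatum and 29 of the 45 that fell. Independent lists would share 2.53 genes of the same sign among the 13685 tested in both. Fisher's exact test gave a two-sided p of 8.52e-15 for the risen and 4.78e-27 for the fallen genes. For calls of either sign it gave 1.05e-31. The test takes genes as independent of each other, which they are not. The log2 fold changes of Ech1 were −3.05 in striatum and −2.51 in cerebellum, those of Cradd −2.79 and −2.74, and those of Cln3 −1.90 and −2.03. Cuedc2 had −1.90 and −1.73, Atpbd4 −1.38 and −1.56, and the endocytic protein Ehd3 −1.10 and −0.73. On the rising side, Snrnp35 had 1.96 and 1.54, Ppp2r3c 1.61 and 1.07, Aars2 1.12 and 0.88, and Dnlz 0.95 and 0.84. Ech1 and Cln3 lie on chromosome 7 (28825217 to 28832247 and 126571207 to 126585817), Cuedc2 on chromosome 19 (46329812 to 46338702) and Cradd on chromosome 10 (95174746 to 95324133). Ppp2r3c lies on chromosome 12 (55278991 to 55302998) and Snrnp35 on chromosome 5 (124483134 to 124491124). Exons of 10 of the 38 genes overlap another counted gene, among them Cln3, Cuedc2, Dnlz, Lrsam1 and Ppp2r3c, and values of overlapping genes are uncertain because the strand setting is not given. The partner of Ppp2r3c, 1110008L16Rik, was itself called higher in cerebellum (log2 fold change 1.09). Genes called in cerebellum had the same sign in striatum in 691 of 1072 cases. As sets the risen and fallen genes shifted the same way there (camera with an estimated correlation, adjusted p of 0.0150 and 0.0161). The striatal median log2 fold changes of these sets were small, 0.04 and −0.08, and the sets include the 38 shared genes. Across genes, which are not independent replicates, Spearman's correlation of the fold changes was 0.166. The shared count was 66 without striatum WT replicate 1. It was 11 without striatum WT replicate 3, 10 without striatum cKO replicate 2, and 3, of which 2 were higher and 1 lower, without either striatum cKO replicate 1 or 3.

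**Figure D4:**
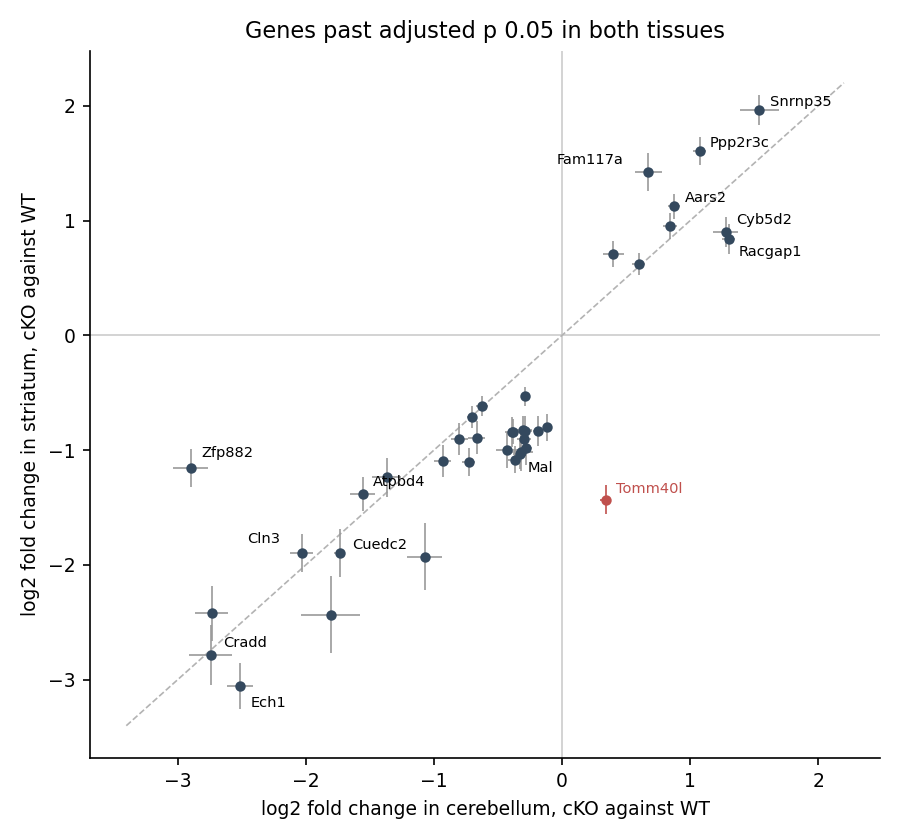
Log2 fold changes, cKO against WT, of the genes past an adjusted p of 0.05 in both tissues, cerebellum on the x axis and striatum on the y axis; bars are SE and the dashed line marks equal changes. On the striatal axis the 38 genes of the same sign run from Ech1 (−3.05) to Snrnp35 (1.96), and Tomm40l is the 1 gene of opposite sign.

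**Figure D5:**
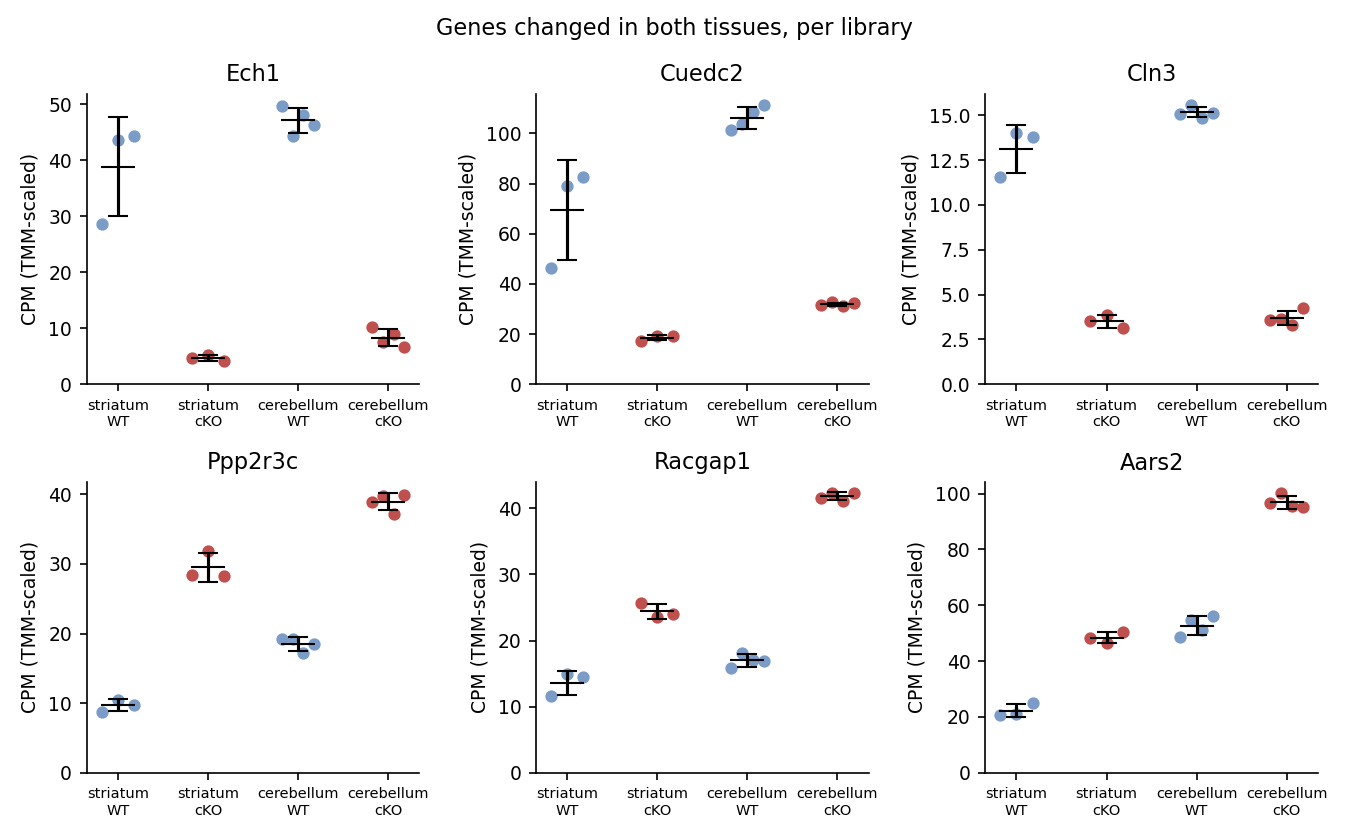
CPM per library of 3 genes that fell and 3 that rose in both tissues; points are libraries, horizontal bars the mean and error bars the SD. Cuedc2 averaged 18.6 CPM in cKO striatum and 31.9 CPM in cKO cerebellum, against 69.3 and 106 CPM in WT.

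Whether the genotype effect differed between the tissues was tested as an interaction. The smallest p belonged to Tomm40l, a mitochondrial import channel homologue, which fell to 37.1% of WT in striatum and rose to 127% in cerebellum (difference in log2 fold change 1.76, SE 0.121, adjusted p = 2.42e-06). Zfp658 fell in striatum (log2 fold change −1.74) and was not called in cerebellum (−0.12). Zfp882 fell in both tissues, by 2.90 in cerebellum against 1.15 in striatum on the log2 scale. Exons of Tomm40l and Zfp882 overlap another counted gene, neither of them called in the same direction. Fbxo9, Slc16a11 and Ccdc120 fell in cerebellum by 0.49 to 0.60, and none of them was called in striatum. Alg12 and Pgm5 rose in cerebellum, with log2 fold changes of 0.55 and 0.52, and were not called in striatum. In total 60 of 15401 tested genes had an interaction by edgeR, 37 with a positive and 23 with a negative difference, and 1793 passed an unadjusted p of 0.05. The count ranged from 17 without striatum cKO replicate 3 to 193 without striatum WT replicate 2. It was 108 without striatum WT replicate 1, 24 without striatum cKO replicate 1, and 19 to 28 without any of the cerebellar libraries. The model of all 14 libraries takes the same dispersion of each gene for both tissues, although striatal samples varied more. In that model the genotype calls were 376 in striatum and 251 in cerebellum, against 54 and 1121 in the separate fits. Striatal spread may thus be understated for the 60 genes. The myelin genes had a larger decrease in striatum than in cerebellum, with a median difference of 0.55 (camera adjusted p = 3.91e-15; 0.537 with an estimated correlation).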

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

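The test of where the shared genes lie on the chromosomes was chosen only after its result was seen, and the removal of each library's length trend was added after the data had been seen. The other tests in this part were set before their results were seen, while the make-up of the splits with large interaction counts was looked up afterwards, and the interaction of the lists was tested without each library only then.

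A test of the difference itself called 60 genes, in the model that takes the same dispersion for both tissues. The difference in log2 fold change, cerebellum minus striatum, was 1.76 for Tomm40l, 1.61 for Zfp658, 0.92 for Alg12, 0.84 for Klhl4, 1.01 for Pgm5 and 0.75 for Clic4. It was −0.76 for Fbxo9, −1.76 for Zfp882, −0.85 for Car10, −0.99 for Slc16a11 and −0.92 for Ccdc120. Of 100 splits drawn within the tissues, out of 700 possible, 4 gave as many genes, the real one included, and the highest of the others gave 117. That share is under 0.05 but close to it. The 3 others each kept the striatal genotypes whole and set 3 cKO and 1 WT cerebellar libraries in the place of WT. In such splits a genotype effect that the tissues share counts as a difference between them. The share therefore does not decide whether the 60 genes arose by chance, and chance is not excluded.

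By camera with a preset correlation 10 lists also differed between the tissues, and 0 did with an estimated one (smallest adjusted p = 0.537). The median difference, cerebellum minus striatum, was 0.55 for myelin, 0.44 for cell cycle, 0.23 for unfolded protein response, 0.68 for interferon response, 0.21 for endothelium and pericyte and 0.28 for oligodendrocyte precursor genes. It was −0.30 for oxidative phosphorylation, −0.26 for ribosomal protein, −0.15 for proteasome and −0.17 for cholesterol synthesis genes. Without striatum WT replicate 1 these 4 were −0.00120, 0.06, −0.00440 and −0.10 and camera passed none of them (adjusted p from 0.0541 to 0.779), nor the endothelial or precursor list, so these 6 lists are not shown to differ between the tissues without that library. The myelin, cell cycle, unfolded protein response and interferon lists passed with the preset correlation whichever library was left out. With an estimated correlation and all libraries their adjusted p was 0.537, 0.537, 0.708 and 0.708. Other splits of the libraries were not tried for these lists, so a difference between the tissues is not firmly shown for them either.

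Among 60 sets of 4 cerebellar libraries, each for a gene level or a library measure, 5 held a library far from the other 3, where chance gives about 1 in 20. They were Atpbd4 at 17.8 CPM and Cacna1i at 165 CPM in WT replicate 3, Prpsap1 at 73.6 CPM in cKO replicate 2, Dnlz at 52.9 CPM in cKO replicate 1, and the share of counts in the top 10 genes, 2.71%, in WT replicate 1.

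The 38 genes that changed with the same sign in both tissues were compared with 100 drawn splits of the samples. Only the real one, 1 of 100, reached 38, and the highest of the others gave 0. Each other split of striatum called 0 genes, so a shared count of 0 was fixed there in advance. The splits therefore do not decide whether the sharing arose by chance. Variants linked to the targeted Thap1 locus would place the genes on chromosome 8, which holds 2 of the 38, while the rest lie on other chromosomes, so linkage is argued against as the whole cause. Reads shared with an overlapping called gene are argued against as the main cause, since 1 of the 38 overlaps a gene called in the same direction in the same tissue. Exons of 20 of the 38 overlap some annotated gene, and 10 overlap a counted one. Partners that were not counted could not be assessed. Uncalled partners may move the same way, as Apobr beside Cln3 did (log2 fold changes of −0.66 in striatum and −0.71 in cerebellum). What also stays open is that these genes may depend on THAP1 in both tissues, or that the cKO line may carry other variants elsewhere in the genome. Neither was tested.

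The lower myelin transcripts of striatal cKO samples kept a median log2 fold change of −0.71 without WT replicate 1, and of −0.82 after each library's length trend was removed. Neither that library nor gene length accounts for them as the whole cause. A smaller share of mature oligodendrocytes would lower all members alike only if no other cells expressed them, which was not tested. After each library's mean over the list was subtracted, 6 of 15 members in striatum still differed between genotypes (limma, adjusted over the list). In cerebellum 4 of 15 did. The members thus fell unequally, but this does not decide between a smaller share, changes of single genes, or both. How much white matter each dissection held was not measured.

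The higher oxidative phosphorylation, ribosomal protein and proteasome transcripts of striatal cKO samples had a pooled median log2 fold change of 0.28 over 171 genes. Without WT replicate 1 it was 0.0316, as would be seen if that 1 library were the source. Oxidative phosphorylation alone kept a median of 0.08 there and passed camera (adjusted p = 0.000273, or 0.842 with an estimated correlation). A small remainder of that list may therefore have another source. The deviations of WT replicate 1 from the mean of the striatal libraries rose with exon length (Spearman's rho 0.557 across genes, which are not independent replicates). In the other striatal libraries rho was −0.228 to −0.309. After each library's length trend was removed the median was 0.17, so gene length and another property of that library cannot be told apart as its cause. No biological explanation was tested.

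For striatum, 10 splits are too few for a share under 0.05. The real one gave 54 genes and 11 lists, and the highest of the others 0 genes and 9 lists. The median of the others was 8 lists, so the number of lists passing camera says little about genotype. In cerebellum 1 of 35 splits, the real one, gave 1121 genes and the highest of the others 9. That other split set the males against the females. The share is under 0.05 and argues against chance, but it is the smallest that 35 splits allow. For the cerebellar lists 3 of 35 splits gave as many as the real 13, with 13 as the highest of the others and 7 as their median. Chance is therefore not excluded for their number.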

How the results depend on the processing

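The removal of length trends (exon-length offset) was chosen only after the data had been seen. No Thap1 value and no gene called in a tissue changed sign under any setting. The striatal and the shared calls, mostly lower, were 2 higher and 1 lower without cKO replicate 1 or cKO replicate 3 of striatum. Of the lists called in striatum, the ribosomal protein median turned to −0.06 without WT replicate 1 and the candidate target median to 0.08 without WT replicate 3. Where a value moved, the cause was not tested. Against 54 genes, striatum gave 151 with DESeq2, 186 with limma-voom, 376 with all 14 libraries in 1 model, 86 with the exon-length offset, 87 at an adjusted p of 0.1, and 3 to 122 when 1 library was left out. The 3 came without cKO replicate 1 or cKO replicate 3, 12 without WT replicate 3 or cKO replicate 2, and 122 without WT replicate 1. Of the striatal calls 3 were made in all 6 of these fits, and of the cerebellar calls 578 of 1121 in all 8. With a sex score as covariate striatum gave 40 genes, 37 of them among the 54, and cerebellum gave 1288. Cerebellum gave 251 genes with all 14 libraries in 1 model, 1773 at an adjusted p of 0.1, and 739 (without WT replicate 3) to 1165 when 1 library was left out. The log2 fold change of Thap1 ranged from −1.66 to −1.15 in striatum and from −0.40 to −0.27 in cerebellum when 1 library was left out. In cerebellum it was −0.34 with DESeq2's size factors and −0.33 with library totals, neither past the threshold. Camera with an estimated correlation called 0 lists in either tissue, against 11 and 13, and fry called 0 and 8. Leaving out 1 library gave 6 (without WT replicate 1) to 14 lists in striatum and 9 to 15 in cerebellum. Genes called in both tissues, 38, numbered 70 with DESeq2 and 3 to 66 when 1 library was left out. The interaction, 60 genes, gave 228 with DESeq2 and 17 to 193 when 1 library was left out. For single named genes, 352 values in striatum stayed on their side of the threshold, 107 weakened past it and 5 strengthened, and in cerebellum 1167 stayed and 75 weakened.

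With the replicate number as a block, striatum gave 15 genes (6 higher and 9 lower, 1 of them a myelin gene), cerebellum 1246, both tissues 13 and the interaction 19. Camera then called 9 striatal lists, without the ependymal (adjusted p = 0.0504) and astrocyte (0.0644) lists, and 14 cerebellar lists, with the ependymal list (0.0385). A block of genotype and replicate across tissues left 1 interaction gene, but it takes same-numbered tissues as 1 animal, and replicate 2 read as female in striatum and male in cerebellum in both genotypes. Same-numbered WT and cKO libraries had deviations correlated at 0.133, 0.0896 and 0.0574 in striatum and 0.340, 0.163, 0.0569 and 0.205 in cerebellum. Every striatal library correlated best with its own number, a hint from the data and not the design, and in cerebellum not all did, so the numbers were not taken to pair the samples. Same-numbered WT and cKO libraries also shared the sex read from their counts in all 7 pairs, so the block carries sex as well.

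In simulated counts with the real dispersions, library sizes and sample numbers, 2.41% of the smallest changes were recovered in striatum and 56.3% in cerebellum, and which of these sets the difference was not tested. A gene called in cerebellum alone is therefore not shown to differ from striatum unless its interaction was called. Interaction calls in turn rest on a dispersion shared by the tissues. For Thap1, counts of 48 to 231 per library limit the precision of its level.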

Other observations

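The test of whether changes scale with the loss of Thap1 was chosen only after its result was seen.

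Some other genes of inherited dystonia were called in cerebellum, where 7.59% of all tested genes were. In cerebellum, Prrt2, which acts in transmitter release, and the chloride channel family gene Ano3 rose, with log2 fold changes of 0.25 (SE 0.0453, edgeR adjusted p = 0.00257) and 0.26 (SE 0.0596, adjusted p = 0.0119). The tubulin gene Tubb4a fell to 85.2% of WT (adjusted p = 0.00778). Of the 21 measured genes of the list 2 rose and 1 fell, or 2 and 2 when adjusted over the list alone, and camera did not pass the list (adjusted p = 0.663). In striatum 0 of 21 were called by edgeR, with log2 fold changes of 0.37 for Prrt2 and −0.23 for Tubb4a. Of 10 measured members of the THAP family and THAP1's partners, 0 were called by edgeR in either tissue, also adjusted over the list alone.

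Genes beside Thap1 on chromosome 8 were mostly not called. In cerebellum Hook3, a linker of organelles to microtubules, fell to 85.2% of WT (edgeR adjusted p = 0.00222) as the 1 called gene of 13, and the list did not pass with camera (adjusted p = 0.102). In striatum Hook3 had a log2 fold change of −0.45 and was not called (adjusted p = 0.459). Of 14 genes of lysosomal glycosaminoglycan breakdown, Gusb fell in both tissues and the other 13 were not called in either.

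A hypothesis was that changes of target genes scale with the loss of Thap1 mRNA, which was 61.2% in striatum and 20.97% in cerebellum. If so, genes changed at least 2-fold in cerebellum should show larger changes in striatum. Among 27 such genes tested in both tissues, 26 had the same sign, and the median ratio of the striatal to the cerebellar log2 fold change was 0.706 (quartiles 0.436 and 1.05). Among the 38 genes called in both tissues it was 1.34 (quartiles 1.02 and 2.29), and 30 of the 38 changed more in striatum. Choosing genes by a large cerebellar change may lower the ratio and choosing them by a striatal call may raise it, so scaling stays open. Reads from an undeleted part of the Thap1 transcript may also hide how much functional mRNA each tissue lost, and this was not tested.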
